A study of Mus musculus with 32 samples.

How the data were processed

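CUT&Tag is an assay in which an antibody guides a transposase to chromatin that carries a given mark, so that DNA around the mark is cut and tagged for sequencing. The series holds 32 samples of mouse oocytes in 16 groups of 2. H3K27me3, the histone mark set by Polycomb repressive complex 2 (PRC2), was profiled in 10 groups, and H2AK119ub, the mark set by Polycomb repressive complex 1 (PRC1), in 6. The wild-type (WT) groups were oocytes at embryonic day 18.5 (E18.5), at postnatal day 1 (P1), non-growing oocytes at day 6 (P6) and growing oocytes at day 7 (P7). The conditional knockout (cKO) groups carried Ddx4-Cre, a recombinase expressed in germ cells. Per the labels, the PRC2 control was Eed heterozygous (one floxed allele) and the PRC2cKO had a floxed and a null Eed allele. The PRC1 control lacked Ring1 and had 1 floxed Rnf2 allele, and its label names Ddx4-Cre as well. The genotype label of the PRC1cKO names Ring1 for the floxed allele where Rnf2 stood in its control, so the floxed gene of that group was not settled, and the groups are called by their names PRC1ctrl and PRC1cKO.

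Per the labels' protocols, Drosophila S2 cells were added to each reaction at a fixed ratio (for example 2000 S2 cells to 1000 oocytes) and reads were 150 bp long. Trim Galore 0.6.10, Bowtie2, Picard 3.0.0, deepTools and SAMtools, with the builds GRCm38, mm10 and dm6, are named in the submitters' processing notes, without their roles. The peak caller, its threshold, any use of the S2 reads for scaling and the way the 2 samples of a group were combined are not given in the sources used here. The authors deposited 1 peak list per group, without a header, and all 16 lists were used. Judged from the values, the deposited signal in the 4th column is summed over each peak, in whole numbers in all 16 lists. These signals are the authors' own values and served to describe, rank or filter peaks within a list. The lowest total signal was also compared between lists, although the scaling of the signals is not known. The other signal columns were not used. Read depth per sample is unknown from these files. As a stand-in for depth, the number of peaks, the covered length and the lowest total signal are given with the results, as ranges over the lists and for some lists singly.

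Genes came from the RefSeq annotation of GRCm38.p6, the build of the lists, with 21887 protein-coding genes on the 19 autosomes, X and Y. The design called for promoters. Because the annotation table used here gives no strand, a window of 1 kb to each side of both annotated gene ends took the place of the promoter, and windows that touched were merged. A gene was called marked when a peak covered at least 1 bp of either window. It lost its mark between lists A and B when it was marked in A and unmarked in B, and gained it in the opposite case. A peak was called shared when a peak of the other list covered at least 1 bp of it. The chance level of shared peaks came from 100 circular shifts of the second list along each chromosome. Exact Clopper-Pearson 95% intervals are given for shares. They cover counting error only, and neighbouring genes and peaks are not independent. With 1 list per group there was no replicate check and no p-value. Differences between control lists of the same stage and mark (WT, PRC1ctrl and PRC2ctrl, 5 comparisons) were computed in the same way as a background. These controls differ in genotype, so that background is not replicate error.

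For 19 gene lists, the net change (genes gained minus genes lost) was set against 10000 random lists of the same size drawn with replacement from all protein-coding genes, with and without matching on gene length in 10 bins. The percentile is the share of random lists with a lower net change, ties counted at 50%, and describes these peak lists only. Genes were drawn singly, so neighbouring list members that share a peak count as separate genes. For lists with clustered members, such as olfactory receptors, the percentile can therefore be too extreme. Because a list with many marked genes has more to lose, each percentile is followed by a matched one, from random lists with as many genes marked in the first list of the comparison. Matching on GC content was planned but needs a genome, which was not used here. Of 1906 listed gene names, 1883 were in the annotation, and 23 were left out. The lists were oocyte growth and maternal effect (53 genes in the annotation), H3K27me3-dependent imprinted (28), canonical imprinted (41), primordial follicle and oocyte transcription (30), meiotic prophase (42), germline identity and genome defence (36), spermatogenesis (41), early zygotic genes (32), Hox clusters (39), developmental transcription factors (95), developmental signalling (57), neuronal ion channels and receptors (45), granulosa and ovarian stroma markers (36), blood and endothelial markers (26), Polycomb and partners (47), cell cycle inhibitors and apoptosis (28), growth signalling and metabolism (36), ribosomal proteins (61) and olfactory receptors (1110). Some genes are in more than 1 list.

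The genes named in the text follow a rule. In each comparison these are the 12 list genes with the largest fall and the 12 with the largest rise in peak-covered length within 5 kb of either gene end, among those that lost or gained the mark, with 3 genes outside the lists each way. Olfactory receptors were left out of this choice. Outside the lists, genes named Gm with a number and genes with Rik in the name were left out too. Ring1, Rnf2, Eed and the Hox clusters are always given. Some genes that the rule selects are not reported here. Members of lists that are named in other sentences were chosen after their values were seen. Groups, comparisons, gene lists, the naming rule and 5 alternatives (a window of 2.5 kb, 50% of the window covered, 50% of the peak overlapped, the 50% of peaks with the highest total signal, and equal numbers of peaks) were fixed before the data were examined. Added later were lists trimmed to equal covered length, the whole gene span with 1 kb to each side, random lists matched on length or on marked genes, the P6 to P7 step in the PRC1 lists and 2 kinds of reference set. In the first, genes were chosen by control lists other than the one compared: marked in WT and in the control of the other line at P6 (or in WT alone at P7), and then early (marked in WT at E18.5 and P1) or late (unmarked at both). In the second, genes were those that the WT lists lost or gained from P6 to P7.

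The calculations were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: after the peaks at 200 genes were removed from the WT P6 H3K27me3 list, the step over 21887 genes recovered 200 losses and 0 false gains. Coverage matched a base-by-base count in 2000 of 2000 windows. In the same simulation, 300 random lists had a mean percentile of 50.6, and a list of 50 genes with 25 removed marks came out at percentile 0. Peaks on every chromosome and contig were counted in the numbers of peaks and in the shares of peaks found again.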

Results

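The lists described H3K27me3 and H2AK119ub in oocytes from shortly before birth, through the non-growing stage, to the start of growth, and in oocytes of conditional knockouts aimed at PRC1 or PRC2. Each held between 49615 and 83994 peaks and covered between 244.2 and 728.3 Mb. The lowest total signal of a peak differed from list to list, between 3754 and 20369, so a total signal that entered 1 list lay below the lowest of another. Genes marked by H3K27me3 numbered 8625, 8781, 9310 and 10065 in WT oocytes at E18.5, P1, P6 and P7. For H2AK119ub the numbers were 15254, 13249, 14821 and 9988. There was 1 list per group, so no difference here has a replicate check, and all intervals cover counting error only.

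Hox genes, which pattern the body axis, carried both marks throughout. All 39 genes of the Hox clusters were marked by H3K27me3 in all 10 lists and by H2AK119ub in all 6. The Hoxa cluster (chromosome 6, 52155367 to 52260880, 11 genes) was covered by H3K27me3 over 95.3% of its length in WT P6 oocytes, and Hoxb (chromosome 11, 96194316 to 96368254, 10 genes) over 96.1%. Hoxc (chromosome 15, 102921131 to 103036856, 9 genes) was covered over 100% and Hoxd (chromosome 2, 74668225 to 74765142, 9 genes) over 97.4%. In the WT P7 list the H3K27me3 shares were 95.8%, 93.5%, 97.9% and 94.4%, and those of H2AK119ub were 90.7%, 66.6%, 81.1% and 82.0%.

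H3K27me3 around birth, from E18.5 to P1, left 649 of 8625 marked genes unmarked (7.53%, interval 6.98 to 8.10%), and 805 genes gained it. Dppa3, a maternal factor that guards DNA methylation in the zygote, went from 0 to 7.64 kb of covered length around its ends. Gata2, a blood and endothelial transcription factor, went from 0 to 6.61 kb, and the imprinted gene Phlda2 from 0 to 6.28 kb. Covered length also grew at the signalling genes Fgfr3, Bmp7 and Ptch1 and at Foxc1, a transcription factor of mesoderm and eye, while Kcnh1, a potassium channel, went from 4.30 kb to 0. The genes that lost the mark included Gja4, the gap junction protein between oocyte and granulosa cells (3.07 kb to 0), Npm2, an oocyte histone chaperone, Zp2, a protein of the egg coat, Khdc3, a maternal effect gene, and Sohlh1, a transcription factor of early oocytes. Outside the lists, the widest changes were at Ms4a13, Zfp629 and Cltb (losses) and Rap1gap2, Plcd1 and Ambn (gains).

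Among the gene lists at this step, oocyte growth genes went from 31 to 28 marked of 53 (percentile 3.91 of random lists, 14.3 of matched ones), germline identity genes from 8 to 12 (percentile 98.7, matched 96.6; Ddx4, Dppa3, Prdm14, Taf7l and Utf1 gained) and Polycomb genes from 11 to 15 (percentile 97.7, matched 93.3; E2f6, Kdm2b, Lcor and Pcgf5 gained). Olfactory receptor genes went from 358 to 316 of 1110 (percentile 0, matched 0), a fall that became a rise of 4 at equal numbers of peaks. In total, 79.5% of the E18.5 peaks (interval 79.3 to 79.8%) were shared with P1, against 31.3% after shifting. With lists trimmed to equal covered length 984 genes lost and 580 gained the mark, so the sign of the net change depended on that setting.

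From P1 to the non-growing oocytes of P6, genes of oocyte growth stood out by loss of H3K27me3. Of the 53 genes, 28 were marked at P1 and 17 at P6, with 13 lost and 2 gained (percentile 0, matched 0, and 0 with matching on length). Zp3 (chromosome 5, 135980105 to 135988624), which encodes the egg coat protein that binds sperm, went from 13.35 kb of covered length to 0. Oosp3 (11.22 kb) and Oosp1 (6.56 kb), encoding oocyte-secreted proteins, Tle6 (10.89 kb), a subunit of the subcortical maternal complex, and Zfp57 (10.91 kb), which protects methylation imprints, also went to 0, while Oosp2 went from 12.65 to 2.00 kb. The others that lost it were Dppa3, Gdf9, H1f8, Mos, Nlrp4f, Oas1d and Padi6, chosen after their values were seen. Primordial follicle genes went from 10 to 3 of 30 (percentile 0, matched 0), losing Cdkn1b, an inhibitor of the cell cycle, Jag1, a Notch ligand, Stat3, Ddx4, Gdf9, Padi6 and Zp3. At the same stage 8 of these 30 genes were marked in PRC1ctrl and 5 in PRC2ctrl, so the WT count of 3 was the lowest of the controls.

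Genes that gained H3K27me3 at P6 included 3 of the genes whose maternal allele is silenced in embryos by H3K27me3 rather than DNA methylation. Otog went from 1.71 to 15.37 kb, Enc1 (chromosome 13, 97241105 to 97253040) from 0 to 9.50 kb and Smoc1 (chromosome 12, 81026808 to 81186414) from 0 to 7.64 kb. That list had 18 marked genes of 28 at P1 and 21 at P6 (percentile 91.4, matched 98.9). Sox2, a pluripotency and neural factor (0 to 6.33 kb), Dll1, a Notch ligand (0 to 9.90 kb), Catsper4, a sperm ion channel (0 to 8.44 kb), Nr5a2, a nuclear receptor (0 to 7.40 kb), and Tdrd7, Fgfr2, Tssk3, Klf1 and Emcn also gained it. Losses included Jag2, another Notch ligand (10.90 kb to 0), and Bak1, which drives apoptosis (10.19 kb to 0); cell cycle inhibitors and apoptosis genes went from 13 to 10 of 28 (percentile 1.36, matched 2.005), but 12 were marked in each of PRC1ctrl and PRC2ctrl at P6. Outside the lists Syt16, Th and Galnt17 lost and Mmp15, Slc25a22 and Npepl1 gained the most covered length. Over all genes, 793 lost and 1322 gained the mark, and 78.8% of P1 peaks (interval 78.5 to 79.1%) were shared, against 34.2% after shifting.

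At the start of growth, from P6 non-growing to P7 growing oocytes, oocyte growth genes lost H3K27me3 again, from 17 to 9 marked (11 lost, 3 gained; percentile 0.075, matched 0). Zar1 (chromosome 5, 72577113 to 72581361), needed for the maternal-to-zygotic transition, went from 13.35 kb to 0, Astl (chromosome 2, 127338639 to 127357655), the oocyte protease that hardens the egg coat, from 13.34 to 0.723 kb, and Bmp15, an oocyte growth factor, from 7.88 kb to 0. Tet3, the maternal DNA demethylase (10.0 kb), Oas1c (10.0 kb) and Oas1e (9.67 kb) went to 0 as well. From E18.5 to P7 the list lost 24 and gained 2 marked genes (percentile 0, matched 0). In the PRC1ctrl lists it went from 16 marked genes at P6 to 6 at P7. Gata1, the red cell transcription factor on X (7959260 to 7976663), went from 20.0 kb to 0, and the imprinted genes Grb10 and Mest from 10.0 kb to 0. Sp110, Bmp6 and Nanos2 lost it too, as did Glod5, Afp and Mn1 outside the lists.

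Genes that gained H3K27me3 at P7 included Etv6 (chromosome 6, 134035700 to 134270158; 0 to 15.18 kb), E2f3 (0 to 14.24 kb), Jade1 (0 to 10.0 kb) and Rbms1 (0 to 8.22 kb) of the H3K27me3-dependent imprinted list, which went from 21 to 26 of 28 (percentile 97.4, matched 100) but from 24 to 25 in PRC1ctrl. Of the meiotic prophase genes, 19 of 42 were marked at P7 after 10 at P6 (percentile 99.8, matched 98.6), with Spo11, the nuclease that starts recombination (0.249 to 13.89 kb), Rec8, the meiotic cohesin (0 to 8.06 kb), and Dmc1, Msh5, Sycp1 and Prdm9 among the 11 gains. In PRC1ctrl this list went from 13 to 12 over the same step, so its rise was seen in WT but not there; the difference was not tested. The Polycomb genes Phf19 (0 to 19.09 kb) and Pcgf2 (0 to 10.47 kb), the DNA methyltransferase gene Dnmt3a (0 to 10.0 kb), Sohlh2, Pecam1 and Ddc gained it, with Cxxc5, Msra and Slc26a11 outside the lists. Olfactory receptors went from 321 to 169 (percentile 0, matched 0). In total 1201 genes lost and 1956 gained the mark, and 65.6% of P6 peaks (interval 65.2 to 65.9%) were shared, against 35.0% after shifting; at equal covered length 1675 lost and 1452 gained it.

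In the WT H3K27me3 lists, in order of stage, marked genes of the other lists numbered 90, 92, 94 and 95 of 95 for developmental transcription factors, 52, 55, 55 and 52 of 57 for developmental signalling, 40, 39, 41 and 39 of 45 for neuronal channels and receptors, 32, 31, 33 and 33 of 36 for granulosa and stroma markers and 20, 20, 21 and 18 of 26 for blood and endothelial markers. They numbered 8, 12, 13 and 17 of 36 for germline identity, 12, 13, 10 and 13 of 28 for cell cycle inhibitors and apoptosis, 21, 21, 23 and 21 of 41 for canonical imprinted genes, 24, 23, 27 and 28 of 41 for spermatogenesis, 16, 15, 15 and 14 of 32 for early zygotic genes, 9, 11, 11 and 14 of 36 for growth signalling and 1, 1, 4 and 6 of 61 for ribosomal proteins. From P6 to P7, Polycomb genes went from 15 to 19 of 47 (percentile 82.4, matched 65.55). They went from 15 to 10 in PRC1ctrl and from 13 to 11 in PRC1cKO, so the rise was seen in WT only.

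**Figure D1:**
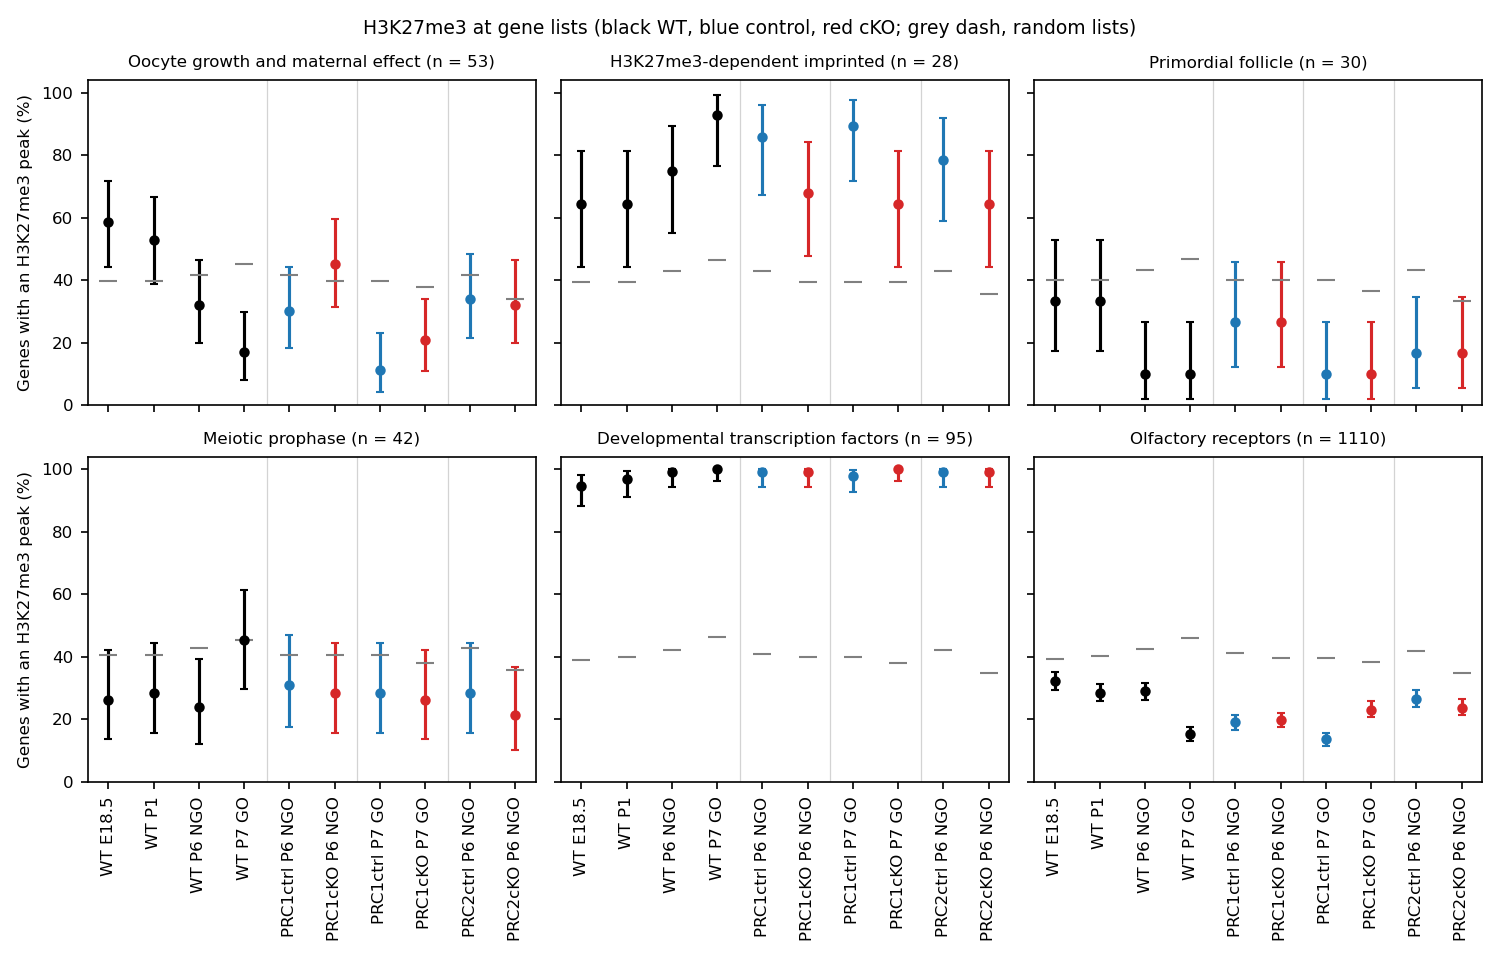
Percent of genes with an H3K27me3 peak (y axis) in 6 gene lists for the 10 H3K27me3 peak lists (x axis), with exact 95% binomial intervals (counting error only); black points are WT, blue controls, red cKO, and grey dashes the median of random lists. Oocyte growth genes fell from 31 of 53 at E18.5 to 9 at P7, while H3K27me3-dependent imprinted genes went from 18 to 26 of 28 in WT and from 24 to 19 in PRC1cKO against PRC1ctrl at P6.

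H2AK119ub around birth, from E18.5 to P1, was lost at 2610 of 15254 marked genes (17.1%, interval 16.5 to 17.7%) and gained at 605. The number gained was higher at equal covered length. Zp3 went from 15.18 kb to 0, Hsf2bp and Iho1, factors of meiotic recombination, from 13.84 and 12.96 kb to 0, and Cdkn2d, an inhibitor of the cell cycle, from 10.54 kb to 0. Zfp57 and Nlrp2, a maternal effect gene, also went to 0, and Nr5a2, Nnat, Tdrd1, Tdrd12, Ybx2 and Actb lost most of their coverage. Gains were at Cyp19a1, the aromatase gene (0 to 8.27 kb), Oosp2 (0 to 7.96 kb), Oosp1, Obox3, Obox5, Zscan4c, Usp17la, Snrpn, Pgk2, Rpl37 and the macrophage markers Adgre1 and Cd68. Oocyte growth genes went from 41 to 31 (percentile 3.46, matched 6.67), and meiotic genes from 30 to 22 (percentile 4.83, matched 4.88). Outside the lists Gga3, Bccip and Kri1 lost and Ces2e, Tgtp1 and Ssxb10 gained the most. Of the E18.5 peaks, 72.6% (interval 72.3 to 72.9%) were shared, against 38.9% after shifting.

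From P1 to P6, 807 genes lost H2AK119ub and 2379 gained it. Kit, the receptor that oocytes need to grow (0 to 9.15 kb), Gdf9, an oocyte growth factor (0 to 8.85 kb), Cdkn2d (0 to 12.69 kb), Jade1 (0 to 10.0 kb), Nr5a2, Ybx2, Tdrd12, Chd3, H13, Omt2b and Rpl32 gained coverage. Zar1l (9.94 kb to 0), Oosp2 (7.96 kb to 0), Mtor, the growth kinase (5.84 kb to 0), Pdpk1, Rpl14, Rpl38, Obox3, Obox6, Rfpl4, Usp17lb, Zscan4c and Pgk2 lost it. Oocyte growth genes went from 31 to 36 (percentile 67.8, matched 62.3) and germline identity genes from 27 to 32 (percentile 85.3, matched 98.8). In PRC2ctrl at P6 the counts were 33 and 26, so the rise of germline identity genes was seen in the WT P6 list alone. Outside the lists Gabarapl1 and Csad were among the widest losses, and Flcn, Tnks1bp1 and Rin2 gained the most. After trimming to equal covered length 1811 genes lost and 1430 gained the mark, and the share of P1 peaks found again was 77.1% (interval 76.7 to 77.4%) at first and 60.0% there.

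From P6 to P7 the H2AK119ub list became one of narrow peaks: the median width went from 7.00 to 2.19 kb and the covered length from 728.3 to 244.2 Mb. At Gata1 the covered length went from 20.0 kb to 0, at Dnmt1, the maintenance DNA methyltransferase, from 16.57 kb to 0, at Zp1, an egg coat gene, from 15.90 kb to 0, and at Dnmt3l, a cofactor of DNA methylation in oocytes, from 20.0 to 1.84 kb. Slc6a4, Ldhc, Acta2, Bak1, Pik3cd, Tsc22d1, H1f8 and Akap4 were also lost, with Arhgef39, Atp4b and Carhsp1 outside the lists. Of the oocyte growth genes, 23 lost and 0 gained the mark (36 to 13; percentile 0.1, matched 0.01), and 32 germline identity genes became 15 (percentile 0.12, matched 1.765) and 31 ribosomal protein genes became 8 (percentile 0.415, matched 0). The 95 developmental transcription factors were marked at both stages. Small gains were seen at Cdkn2b (0 to 3.86 kb), Rb1, Syce1, Rbbp4, Prdm9, Tdpoz5, Mga, Mtor, Mkrn3, Bbx, Rpl14 and Kdm5b, and outside the lists at Cyp2a5, Krt26 and Tdg. In all, 5263 genes lost and 430 gained the mark, and 48.6% of P6 peaks (interval 48.2 to 49.0%) were shared, against 27.7% after shifting. At equal covered length these counts turned round to 870 lost and 5069 gained, and the net change of oocyte growth genes to a gain of 1. Trimming cut the P6 list alone, down to its peaks of highest total signal, so this turn does not argue against a loss. It cannot part a loss of the mark from a difference in coverage, so a direction was not settled apart from coverage.

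Both marks were found together more often than independent lists would give. In WT oocytes 7483, 7541, 8385 and 7794 genes carried both at E18.5, P1, P6 and P7, where independent lists would share 6011, 5315, 6304 and 4593. At Emx1, a forebrain transcription factor, both marks covered 20000 bp at all 4 stages, as they did at Erg, Gata1, Gdf10, Hoxb3, Hoxc6 and Hoxa3 at E18.5 and P6. A length of 20000 bp is the whole window of these genes. Only members of the gene lists, without olfactory receptors, were ranked here, so the longest shared coverage over all genes was not sought. For each stage 12 genes were kept, with ties in alphabetical order, so a gene not named at a stage may also have reached it there. Gli1 and Pax2 reached the same length at E18.5, and Hoxc4 and Kcnq1 at E18.5 and P1. Dlk1, Gata5, Hunk and Otx2 did so at P1, Chrna4 and Grik3 at P1 and P6, and Col1a1, Dnmt3l and Gli2 at P6. At P7 the list genes with the longest shared coverage included Emx1, Grik3, Wnt11 (19611 bp), Tbx2 (19334 bp), Tbx1, Hoxa10, Bmp7, Hoxa3, Six3, Pdgfrb and Wnt10a. Of the oocyte growth genes, 27, 20, 15 and 6 carried both marks at the 4 stages. H3K27me3 without H2AK119ub was seen at 1142, 1240, 925 and 2271 genes. The H2AK119ub list covered 244.2 Mb at P7 beside 728.3 Mb at P6, so the rise to 2271 cannot be told apart from that difference in coverage. Trimmed to equal covered length, 4347 genes carried both at P7, where independent lists would share 2138.

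**Figure D2:**
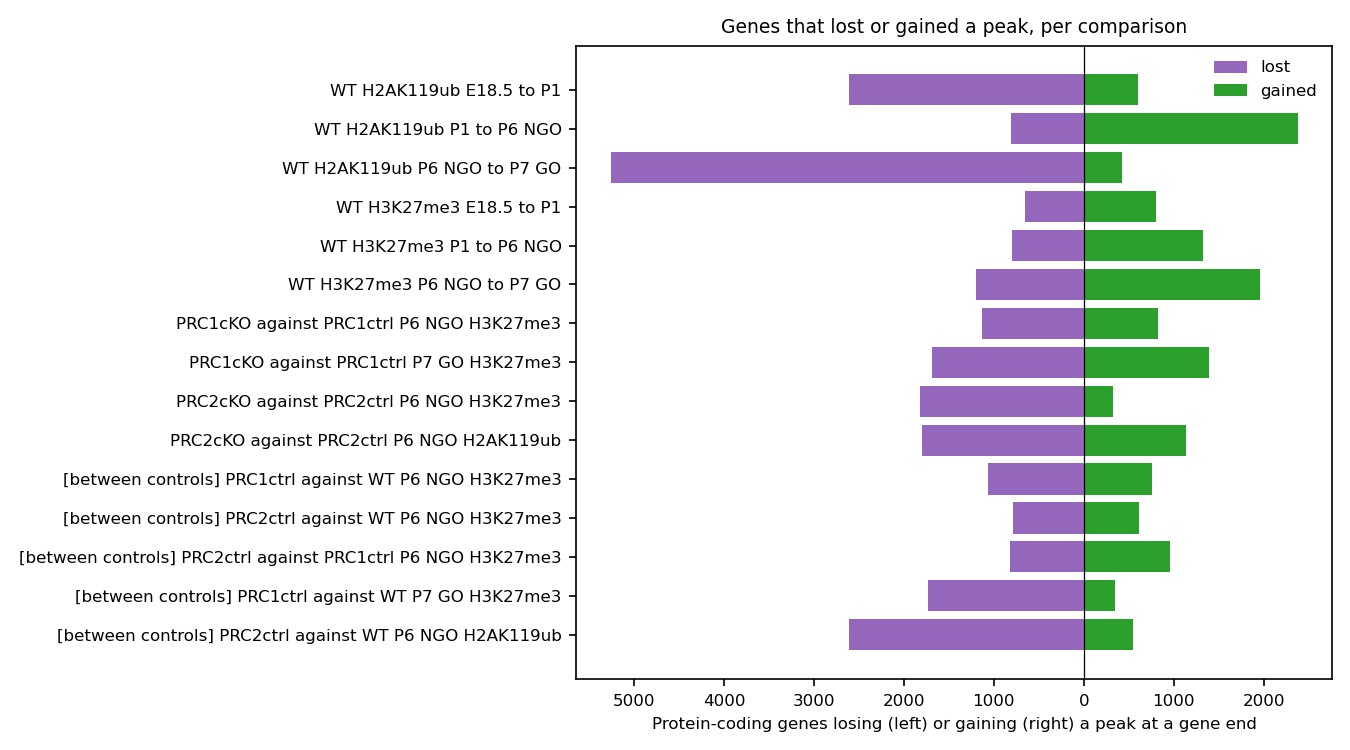
Number of protein-coding genes (x axis) that lost (purple, left) or gained (green, right) a peak at a gene end in each comparison (y axis); lines marked "between controls" compare control lists of the same stage and mark. PRC1cKO at P6 lost 1126 and gained 825, beside 1069 and 760 for PRC1ctrl against WT.

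The cKO comparisons ask which marks depend on PRC1 and PRC2 in oocytes. Of the targeted genes, Ring1 (chromosome 17, 34020792 to 34024680), Rnf2 (chromosome 1, 151469398 to 151500991) and Eed (chromosome 7, 89954654 to 89980976) had no H3K27me3 peak at their ends in any of the 10 lists. By the rule of a peak within 1 kb of a gene end, H2AK119ub marked Ring1 in all 6 lists and Rnf2 and Eed in WT P6 alone; within 5 kb, Eed also had 2.198 kb of covered length in PRC2ctrl. A histone mark at a gene does not show its deletion, so these values check no genotype.

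In PRC1cKO non-growing oocytes at P6, H3K27me3 was missing from genes of the H3K27me3-dependent imprinted list, with 24 of 28 marked in PRC1ctrl and 19 in PRC1cKO. The loss was 20.8% of the marked genes of the list, beside 12.5% of all marked genes (percentile 0.35, but 10.4 in matched lists). The 5 genes were Smoc1 (10.0 kb to 0), Etv6 (13.03 kb to 0), Enc1 (9.00 to 1.05 kb), Otog (7.03 to 2.43 kb) and Mbnl2. Etv6 was unmarked in WT at this stage, so it differed between the controls too; among the 21 list genes marked in both WT and PRC2ctrl, 0 were unmarked in PRC1ctrl and 3 in PRC1cKO. Further losses were at Etv5, a spermatogonial stem cell factor (7.18 kb to 0), Esr2, the granulosa cell estrogen receptor, Tssk3, Sycp1, Tdpoz3 and Usp17ld, and outside the lists at Bpifb3, Dnaic1 and Foxo6. Oocyte growth genes went the other way, from 16 to 24 of 53, with 8 gained and 0 lost. The percentile was 100 (matched 99.95), with each gene counted as independent, also where neighbours may share a peak. Oosp2 (chromosome 19, 11647284 to 11660559) went from 0 to 8.91 kb, Dnmt1 (chromosome 9, 20907206 to 20959888) from 0 to 5.06 kb, Nlrp2 from 0.433 to 4.44 kb and Zfp57 from 0 to 3.495 kb. Part of this rise lay in the control: Oas1c went from 3.17 to 13.56 kb but had 10.0 kb in WT, and in PRC2ctrl Nlrp2 had 10.32 kb and Oosp2 6.03 kb. Nlrp14, Oosp1 and Oosp3, named after their values were seen, completed the 8. Among the 34 oocyte growth genes unmarked in both WT and PRC2ctrl, 2 were marked in PRC1ctrl and 7 in PRC1cKO. Sall4, Fgfr1, Zdbf2, Gm20767, Bcl2, Rb1 and Usp17lb also gained coverage, and outside the lists Slco1a4, Kir3dl1 and Clec4a2.

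Over all genes, 1126 of 9001 lost H3K27me3 in PRC1cKO at P6 (12.5%, interval 11.8 to 13.2%) and 825 gained it. Against WT, PRC1ctrl lacked 1069 genes and gained 760, so the totals were of the size seen between controls. Late genes, unmarked at E18.5 and P1 and marked at P6 in WT and PRC2ctrl, were unmarked in 19.9% of 638 cases in PRC1ctrl (interval 16.9 to 23.2%) and in 42.2% in PRC1cKO (interval 38.3 to 46.1%). For 7282 early genes the shares were 5.38% (4.88 to 5.93%) and 6.02% (5.48 to 6.59%). Of the genes in these sets, 185 late and 248 early ones were unmarked in PRC1cKO alone, and 43 late and 202 early ones in PRC1ctrl alone. Late genes thus lost the mark at a higher rate. They did not make up most of the losses when reverse changes are left out, but reverse changes offset most early losses and few late ones. Peaks shared made up 78.8% of the control list (interval 78.5 to 79.2%), against 35.7% after shifting. Coverage of the Hox clusters was 100%, 89.5%, 100% and 100% (a to d) in PRC1ctrl and 100%, 91.1%, 100% and 92.9% in PRC1cKO.

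In PRC1cKO growing oocytes at P7, 7 of 25 H3K27me3-dependent imprinted genes lost the mark and none gained it, which is 28.0% beside 19.5% of all marked genes (percentile 0.09, but 12.5 in matched lists). These were Smoc1 (17.47 kb to 0), Etv6 (12.32 kb to 0), Enc1, Jade1, Mbnl2, Rbms1 and Tle3. Phf19 (17.41 kb to 0), Dll1 (14.65 kb to 0), Bmp7, a bone morphogenetic protein (17.25 to 1.11 kb), Sohlh2, a transcription factor of primordial oocytes (12.20 kb to 0), Etv5, Pecam1, Cd81, Piwil1, Majin and Cdkn1c lost it as well, with Akna, Cd276 and Msra outside the lists. Genes with more coverage in PRC1cKO included Gata1 (0 to 19.59 kb), Astl (0 to 14.13 kb), Zar1 (0 to 10.32 kb), Dkk1, a Wnt inhibitor (0 to 13.62 kb), Slc6a4, Foxc1, Fgf8, Dio3, Cbx8, Cdkn2b, Ugt8a and Pcgf1, and outside the lists Rph3a, Efna5 and Foxp4. Fgf8 (12.65 kb), Dio3 (11.35 kb) and Cbx8 (11.26 kb) were covered in WT at P7 as well, so PRC1ctrl was the low list for these 3. The same held for 645 of the 1395 genes that gained the mark in PRC1cKO, which WT marked at P7 too. Among the 645 were 2 developmental transcription factors. Oocyte growth genes went from 6 to 11 (percentile 98.0, but 69.9 in matched lists) and olfactory receptors from 151 to 257 (percentile 100, matched 99.95). The PRC1cKO list held 67213 peaks with a lowest total signal of 5094, beside 61336 and 7218 in PRC1ctrl, so weaker peaks may have entered it. The covered share of X relative to autosomes was 0.413 in PRC1ctrl and 0.723 in PRC1cKO, beside 0.923 and 0.968 at P6.

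The step from P6 to P7 was smaller in the PRC1cKO lists for the genes that changed in WT. The X to autosome ratio at P7 was also higher in PRC1cKO (0.723) than in PRC1ctrl (0.413), as an inactive X in ovarian somatic cells would give. Somatic chromatin or a difference in staging could thus give a smaller step, and neither was tested. Of the 1201 genes that WT lost over this step, 13.9% were marked in PRC1ctrl at P7 (interval 12.0 to 16.0%) and 44.96% in PRC1cKO (interval 42.1 to 47.8%), after 61.0% and 64.5% at P6. Of the 1956 genes that WT gained, 54.9% were marked in PRC1ctrl at P7 (interval 52.6 to 57.1%) and 21.6% in PRC1cKO (interval 19.8 to 23.5%), after 20.7% and 13.5% at P6. Late genes (marked in WT at P7, unmarked at E18.5 and P1) were unmarked in 35.0% of 2460 cases in PRC1ctrl (interval 33.1 to 36.9%) and in 68.3% in PRC1cKO (interval 66.5 to 70.2%). In total 1689 genes lost (19.5%, interval 18.6 to 20.3%) and 1395 gained the mark against PRC1ctrl, beside 1732 and 345 for PRC1ctrl against WT. Losses at both P6 and P7 numbered 341, where independent lists would share 75.02 of the 7276 genes marked in both controls. Gains at both numbered 175, where independence gives 27.66 of the 11484 genes unmarked in both controls. Gains exceeded independence too, so the shared losses do not by themselves show an effect of the knockout. No overlap between control comparisons was set beside them. Peaks shared made up 68.5% (interval 68.1 to 68.9%), against 32.4% after shifting, and at equal covered length the net change turned from -294 to 110 genes. Hox clusters were covered over 94.9%, 84.6%, 100% and 90.4% in PRC1ctrl and 100%, 95.4%, 100% and 95.8% in PRC1cKO.

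**Figure D3:**
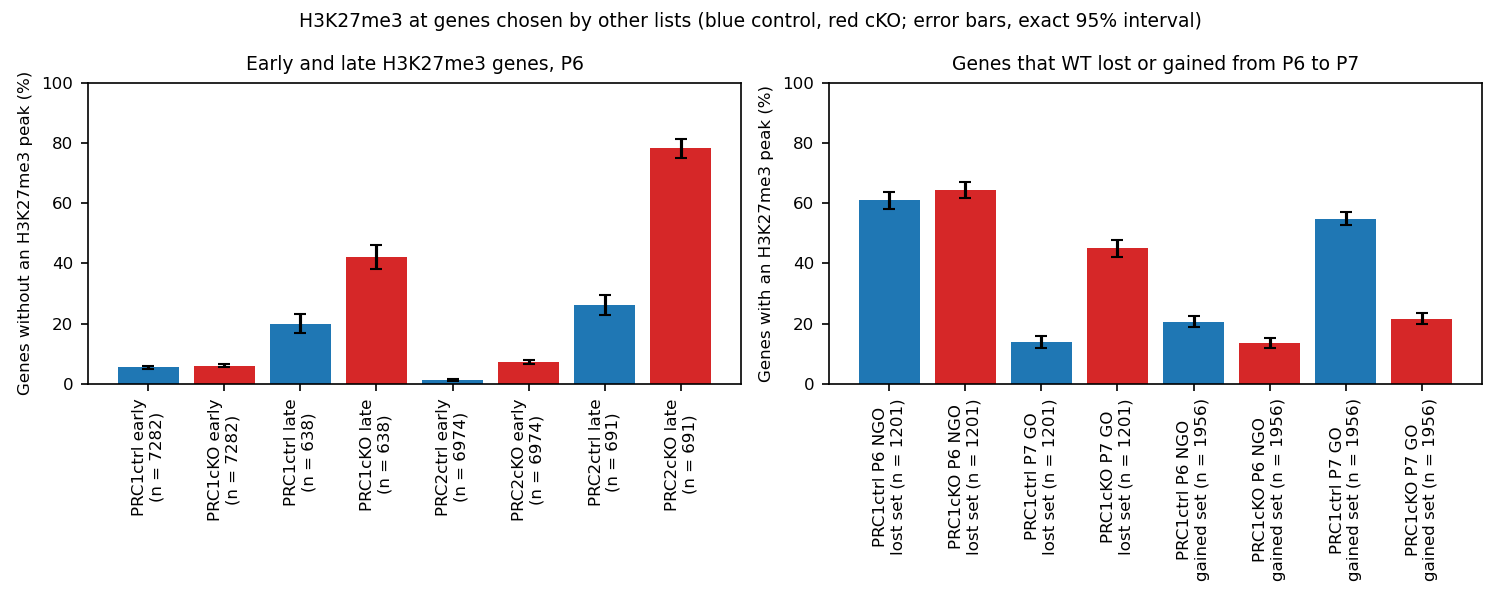
Left, percent of genes without an H3K27me3 peak at P6 (y axis) among early and late genes chosen by other control lists, and right, percent of genes with a peak among those that WT lost or gained from P6 to P7; blue bars are controls, red bars cKO, error bars exact 95% intervals. Late genes without a peak made up 19.9% in PRC1ctrl and 42.2% in PRC1cKO, and 44.96% of the genes lost by WT were marked in PRC1cKO at P7 beside 13.9% in PRC1ctrl.

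In PRC2cKO non-growing oocytes at P6, H3K27me3 remained at the genes where Polycomb is best known. All 39 Hox genes and 94 of 95 developmental transcription factors were marked in both PRC2ctrl and PRC2cKO, and coverage of the Hox clusters was 100%, 100%, 100% and 100% in PRC2ctrl and 100%, 96.1%, 100% and 100% in PRC2cKO. The widest losses included genes that WT oocytes marked at P6 but not at E18.5 or P1, namely Catsper4 (chromosome 4, 134211965 to 134227431; 11.78 kb to 0), Dll1 (chromosome 17, 15367354 to 15376932; 11.40 kb to 0), Otog (10.86 to 1.27 kb), Smoc1 (7.28 kb to 0), Enc1 (7.11 kb to 0), Tdrd7, Etv5 and the PRC1 gene Phc2. Piwil4, a piRNA pathway gene (9.10 kb to 0), Akap3 and Odf1, components of the sperm tail, and Tdpoz4, all marked in WT from E18.5 on, lost it too. Spermatogenesis genes went from 26 to 19 of 41 (percentile 2.47, but 14.7 in matched lists) and H3K27me3-dependent imprinted genes from 22 to 18 (percentile 11.0, matched 52.6; Rbms1 was the fourth). Asgr2, Cdcp3 and Ly6g6g led the losses outside the lists. Gains were few: Cdkn2b, an inhibitor of the cell cycle (chromosome 4, 89306289 to 89311032), went from 0 to 10.73 kb, Mkrn3, Meioc and Dcn gained a peak at a gene end, and Vmn1r50, Defa38 and Vmn1r37 did outside the lists. Oocyte growth genes numbered 18 and 17.

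Over all genes 1817 of 9142 lost H3K27me3 in PRC2cKO (19.9%, interval 19.06 to 20.7%) and 324 gained it, beside 783 and 615 for PRC2ctrl against WT. Late genes were unmarked in 26.1% of 691 cases in PRC2ctrl (interval 22.8 to 29.5%) and in 78.3% in PRC2cKO (interval 75.03 to 81.3%), and the 6974 early genes in 1.20% (0.962 to 1.49%) and 7.27% (6.67 to 7.90%). Peaks shared made up 68.7% (interval 68.3 to 69.1%), against 30.3% after shifting. The PRC2cKO list covered 428.6 Mb beside 558.4 Mb in PRC2ctrl, with a lowest total signal of 6790 beside 10510. At equal covered length 840 genes lost and 927 gained the mark, and the excess of unmarked late genes fell from 52.2 to 12.5 percentage points. Trimming removes the weakest peaks of the control, so it does not part a loss of the mark from a difference in coverage between lists.

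H3K27me3 was lost at many of the same genes in both knockouts. At P6, 436 genes lost it in PRC1cKO and in PRC2cKO, where independent lists would share 93.5; among the 8184 genes marked in both controls, 436 were shared and 99.4 would be by independence. The named genes Smoc1, Enc1, Otog and Etv5 were among them. Gains in both numbered 69, where independence gives 12.2. In opposite directions, 193 genes gained the mark in PRC1cKO and lost it in PRC2cKO (68.5 by independence). The reverse, lost in PRC1cKO and gained in PRC2cKO, was seen at 31 genes (16.7 by independence). Opposite changes thus exceeded independence too, so the shared losses do not by themselves show a shared effect of the knockouts. No overlap between control comparisons was set beside them. These comparisons share no samples. At equal covered length 180 genes were lost in both, where independence gives 43.8.

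Among the other lists, from PRC1ctrl to PRC1cKO at P6, H3K27me3 went from 26 to 24 canonical imprinted genes, 12 to 13 cell cycle and apoptosis genes, 15 to 13 Polycomb genes, 13 to 12 meiotic genes, 211 to 219 olfactory receptors and 14 to 12 early zygotic genes, with 24 spermatogenesis and 8 primordial follicle genes in each. At P7 it went from 13 to 10 cell cycle and apoptosis genes, 13 to 16 germline identity genes, 38 to 41 neuronal genes, 10 to 12 early zygotic genes, 29 to 31 granulosa and stroma markers, 93 to 95 developmental transcription factors, 2 to 4 ribosomal protein genes and 11 to 9 growth signalling genes. From PRC2ctrl to PRC2cKO it went from 23 to 22 canonical imprinted genes, 16 to 12 Polycomb genes, 16 to 11 early zygotic genes, 12 to 10 cell cycle and apoptosis genes, 12 to 9 meiotic genes, 295 to 264 olfactory receptors, 33 to 31 granulosa and stroma markers, 55 to 53 developmental signalling genes, 40 to 39 neuronal genes, 13 to 11 germline identity genes and 3 to 0 ribosomal protein genes, with 22 blood and endothelial markers and 12 growth signalling genes in each.

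H2AK119ub in PRC2cKO non-growing oocytes was lost at 1795 of 12759 marked genes (14.1%, interval 13.5 to 14.7%) and gained at 1140, beside 2606 and 544 for PRC2ctrl against WT. Foxo3, which holds primordial follicles in arrest (chromosome 10, 42181845 to 42276695), went from 2.68 to 13.82 kb, Cdkn2d (chromosome 9, 21288459 to 21291421) from 0 to 6.47 kb and Figla, a transcription factor of early oocytes, from 1.13 to 5.90 kb. Kdm5b, Meioc, Omt2a, Slc22a2, Usp17le, Cd68, Chd3, Eef1a1 and Stat3 gained coverage too, with Spint2, Rsad2 and Myo9b outside the lists. Sycp3 (7.497 kb to 0) and Syce1, parts of the synaptonemal complex, Zp2 (6.71 kb to 0), Cyp19a1 (6.78 kb to 0), the sperm genes Ddx25 and Adam2, and Kcnh1, Ybx2, Sub1, Akt2, Tdrd9 and Tcstv1 lost coverage, with Pramel3, Clrn2 and Alpk1 outside the lists. For 4 of these genes, chosen after their values were seen, the controls differed too: in WT Foxo3 had 12.08 kb, Cdkn2d 12.69 kb, Sycp3 0 and Syce1 1.19 kb. Spermatogenesis genes went from 33 to 27 (percentile 2.39, but 14.7 in matched lists), and 27 of 28 H3K27me3-dependent imprinted genes were marked in each. Shared peaks made up 71.6% (interval 71.2 to 72.0%), against 30.2% after shifting. At equal covered length 805 genes lost and 2526 gained the mark. Coverage of the Hox clusters was 96.9%, 70.9%, 94.0% and 100% in PRC2ctrl and 92.5%, 66.5%, 94.8% and 89.1% in PRC2cKO.

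**Figure D4:**
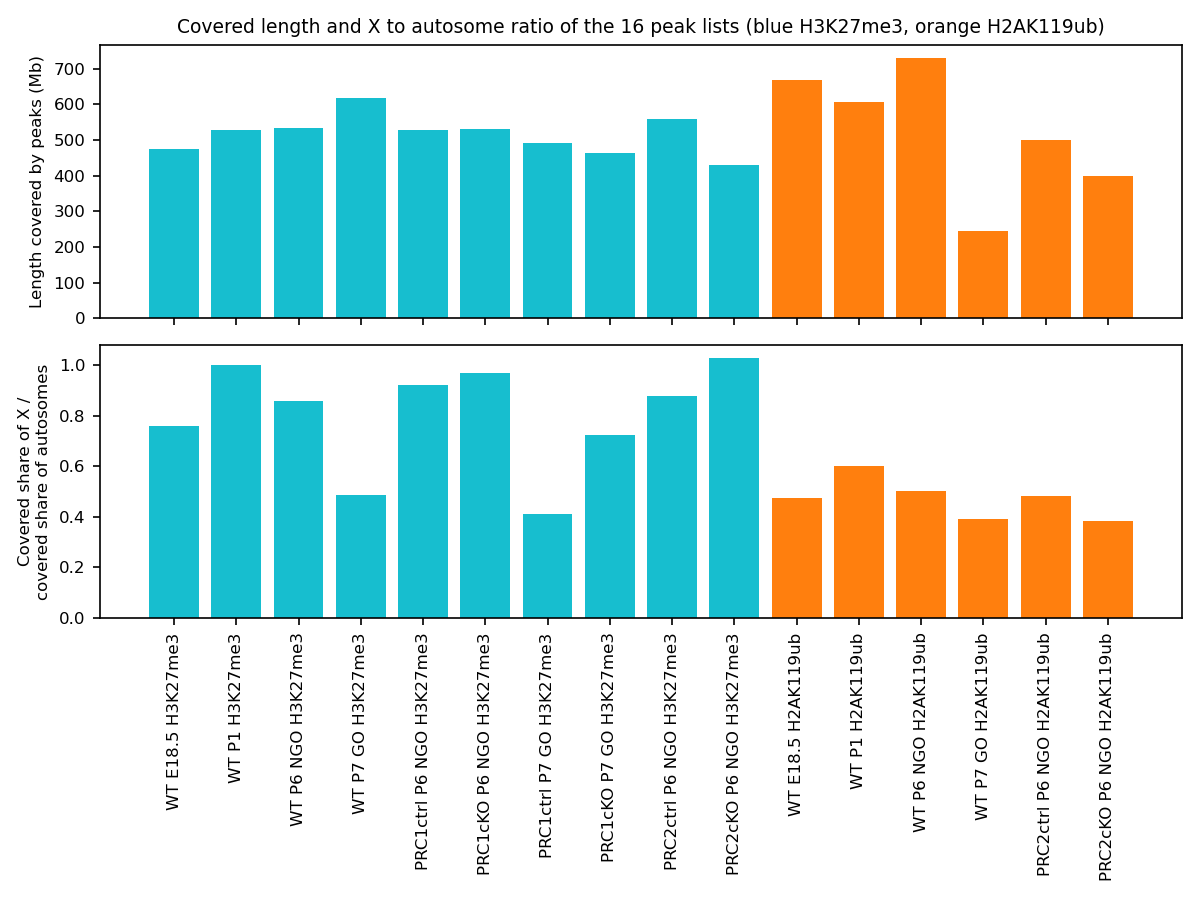
Length covered by peaks in Mb (upper y axis) and the covered share of chromosome X divided by that of the autosomes (lower y axis) for the 16 lists (x axis), blue for H3K27me3 and orange for H2AK119ub. The WT P7 H2AK119ub list covered 244.2 Mb, the least, and the X to autosome ratio of H3K27me3 was 0.485 in WT and 0.413 in PRC1ctrl at P7.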

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

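Here the tests of the X to autosome ratio, those that compare covered lengths, those of covered length at late genes and the comparisons of the step from P6 to P7 in the PRC1 lists were chosen after the results were seen.

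Peaks on chromosome Y, on which female cells should give no signal, were present in 3 lists: 27, 24 and 16 peaks in the WT H3K27me3 lists of E18.5, P1 and P6, against 0 in the other 13 lists. On the mitochondrial chromosome, which carries no histones, the WT P7 H2AK119ub list had 1.86% of its signal, above the PRC1ctrl and PRC2ctrl lists, where the highest share was 0.373%. From P6 to P7 the number of genes with H3K27me3 went up by 755 in WT but fell by 323 in PRC1ctrl and fell by 316 in PRC1cKO, in opposite directions; the difference was not tested. Every sign turned at equal covered length, where the changes were -223, 102 and 539. Olfactory receptor genes with H3K27me3 fell by 152 in WT and fell by 60 in PRC1ctrl but went up by 38 in PRC1cKO; this difference was not tested either. With 1 list per group, none of these can be set against a spread between samples.

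Oocyte growth genes lost H3K27me3 in WT oocytes from E18.5 to P7. More of the genome covered by the E18.5 list is argued against by the lengths themselves. The difference from the P7 list was -144.3 Mb, so E18.5 had the shorter coverage. But the E18.5 list had more peaks (83994 against 61088) and a lower floor of total signal (6886 against 14139). Covered length does not test whether weaker peaks entered that list, so this stays open. A falling share of ovarian somatic chromatin, where an inactive X would carry H3K27me3, would lower the X to autosome ratio of covered share. From E18.5 to P1 that ratio changed by 0.2415, a rise, which argues against it for that step, but it changed by -0.1407 from P1 to P6 and by -0.375 from P6 to P7, where most of the genes were lost, so a somatic contribution may explain part of the loss at both of these steps. A change of the oocytes with age, which the design names, stays open and was not tested apart from list quality.

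Genes that gained H3K27me3 late were without it in PRC1cKO and PRC2cKO more often than in their controls, by 22.3 and 52.2 percentage points, against 0.632 and 6.07 for early genes. Weak peaks near the threshold of the lists may explain such a loss, but early genes matched on total signal showed -2.03% of the PRC1cKO excess, which argues against it there, and 35.1% of the PRC2cKO excess, between the bounds set for and against, so in PRC2cKO weak peaks and a specific loss cannot be told apart. Fewer bases covered by the PRC1cKO list is argued against at P6, for late and imprinted genes, because that list covered 2.24 Mb more than its control, and at P7 for the imprinted list, where the net loss at equal covered length was 7 genes. Fewer bases covered by the PRC2cKO list and a true loss cannot be told apart from the values at equal covered length, 12.5 points for late genes and 1 gene for the imprinted list, because a true loss also shortens the coverage. A role of PRC1 in placing late H3K27me3 stays open as a hypothesis, as do batch, dissection and staging differences between PRC1ctrl and PRC1cKO; deciding between them would take lists of separate samples, to set the excess against a spread, and H2AK119ub in PRC1cKO oocytes, and neither was among the lists.

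H3K27me3 peaks at Hox and developmental genes were present in the PRC2cKO list. Chromatin of ovarian somatic cells could be their main source, and the test of this decided nothing: the median percentile of signal per base over the granulosa and stroma marker genes was 97.7, but only the 31 of 36 with a peak were scored, and all genes with a peak had a median of 88.5, already above the bound of 80. The X to autosome ratio, 0.877 in PRC2ctrl and 1.03 in PRC2cKO, the highest of the 16 lists, goes with a somatic source, which stays open. Marks that persisted from before the deletion of Eed, incomplete deletion, and a threshold set within each list could each give these peaks, and none of them was tested.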

How the results depend on the processing

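Lists trimmed to equal covered length and the gene span were chosen after the data were seen, as were the late-gene and step-set values under the settings. No paired analysis was possible because each group had 1 list, and leaving out a replicate was not possible for the same reason. Of 190 alternative values of the 35 results that answer a comparison, 140 stayed within the limits set and 50 moved; these are counts and shares without a sign, which cannot reverse. Of 442 values for 77 other results, 301 stayed, 110 moved and 31 reversed, all 31 of them net changes. The cause was not tested, except that trimming lowers the share found again wherever peaks are removed from the second list only. Equal covered length gave, for H2AK119ub, E18.5 to P1: 968 gained, 82.3% shared; P1 to P6: 1811 lost, 1430 gained, net -381, 60.0% shared; P6 to P7: 870 lost, 5069 gained, net 4199, 98.3% shared, and net changes of 2 germline identity, 49 olfactory receptor, 1 oocyte growth and 2 ribosomal protein genes. For H3K27me3 it gave, E18.5 to P1: 984 lost, net -404, 68.5% shared; P1 to P6: 77.8% shared, olfactory receptors -1; P6 to P7: net -223, 52.3% shared; PRC1cKO at P6: 78.4% shared; PRC1cKO at P7: net 110, 74.2% shared; PRC2cKO: 840 lost, 927 gained, net 87, 94.8% shared, olfactory receptors 85. For H2AK119ub in PRC2cKO it gave 805 lost, 2526 gained, net 1721, 93.4% shared and olfactory receptors 30. Between controls the nets were -242 (PRC2ctrl against PRC1ctrl), 97 (PRC1ctrl against WT at P7) and 1705 (PRC2ctrl against WT, H2AK119ub). From P6 to P7 they were 102 in PRC1ctrl and 539 in PRC1cKO, and from E18.5 to P7 in WT -303 for H3K27me3 and 3698 for H2AK119ub. Both marks were at 4347 genes in WT P7, and 180 genes were lost in both knockouts. Equal numbers of peaks gave shares of 82.5% (H2AK119ub P1 to P6), 40.7% (P6 to P7, with 274 gained), 85.0%, 76.8% and 72.2% (H3K27me3 steps in order), 79.3% and 66.3% (PRC1cKO at P6 and P7), 71.8% and 68.1% (PRC2cKO, H3K27me3 and H2AK119ub). Reversed there were olfactory receptors at 14 (H2AK119ub P1 to P6), 4 (H3K27me3 E18.5 to P1) and -10 (P1 to P6), and the P6 nets against WT, 441 for PRC1ctrl and 494 for PRC2ctrl. With the gene span, the H3K27me3 net from E18.5 to P1 was -50. With 50% of the window covered, olfactory receptors from P1 to P6 changed by 4 (H2AK119ub) and -8 (H3K27me3), by -5 with the window of 2.5 kb and by -12 with the stricter threshold (both H3K27me3). The stricter threshold gave shares of 73.1%, 77.6% and 49.6% (H2AK119ub steps in order), 81.5% (H3K27me3 E18.5 to P1), 80.2% and 70.7% (PRC1cKO at P6 and P7), 69.7% and 75.8% (PRC2cKO, H3K27me3 and H2AK119ub). Overlap of 50% of the peak gave 65.1%, 73.6% and 15.0% (H2AK119ub), 75.7%, 72.3% and 60.7% (H3K27me3), 70.6% and 55.03% (PRC1cKO) and 55.2% and 55.3% (PRC2cKO) in the same order. Read depth was not known, so what it limits was not tested.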

Other observations

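The tests of late genes under the settings and of the genes that WT lost or gained from P6 to P7 were chosen after the results were seen.

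The excess of unmarked late genes lay between 22.3 and 29.5 percentage points in PRC1cKO over the alternatives. In PRC2cKO it lay between 49.4 and 60.1 points, except at equal covered length, where it was 12.5. Of the genes that WT lost from P6 to P7, the share marked in PRC1cKO at P7 exceeded that in PRC1ctrl by 26.6 to 35.9 points over the alternatives. For the genes that WT gained, the difference was between -27.2 and -34.8 points.

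Within the PRC2cKO H3K27me3 list, Hox genes had a median percentile of signal per base of 99.7 among all peaks, beside 88.5 for all genes with a peak. In the PRC2ctrl list the Hox median was 99.5, so the high value is not particular to PRC2cKO. The median repeats few peaks, since Hoxa, Hoxb, Hoxc and Hoxd lay under 1, 2, 1 and 1 peaks in PRC2cKO.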
